A study of Homo sapiens with 8 samples.

How the data were processed

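Poly(A) RNA was sequenced from 2 established human lines that the labels give as small cell lung cancer, NCI-H1688 and NCI-H146. Each line had been infected with lentivirus carrying either a control short hairpin RNA (shRNA) or an shRNA against KLF9, and selected with puromycin before RNA was collected. Per the labels' protocols, poly(A) RNA was fragmented and copied with random primers before adaptor ligation and PCR. The submitters' processing notes name STAR 2.5.1, DESeq2 and the human build GRCh38 (hg38), without saying which step each was used for. The program that counted reads, the annotation and the DESeq2 version were not given in the sources used here.

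The 2 lines came in separate tables with different units. For NCI-H146 the deposited values were whole-number read counts per gene, with 17169 genes, and the smallest total over the 4 libraries was 2 counts, so genes with lower totals were not analysed here. For NCI-H1688 the deposited values were TPM, a length-scaled abundance, with 58434 rows, of which 30042 were at 0 in all 4 libraries. The TPM columns summed to between 843186 and 885808, and the median ratio of each library to the geometric mean of the genes was 1.002615 in all 4 libraries. The values had therefore been scaled once more between libraries before deposit, by a step that no label records. Rows of the NCI-H1688 table that shared a gene name (1599 rows), or came to share a current symbol, were not summed. The row with the highest mean was kept and the others were dropped, which left 56866 genes. A renamed row never displaced a row that already bore the symbol. Gene names were brought to current symbols through the GENCODE 29 annotation and a RefSeq gene table, and 57189 of the NCI-H1688 names and 17115 of the NCI-H146 names were current or could be mapped. Coordinates are those of GENCODE 29 on GRCh38. Neither table records whether counting used strand, so reads of overlapping genes could not be told apart, and reads of near-identical genes could be split between them.

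Each line was fitted alone because the tables had been normalized separately, and no level was tested across them. NCI-H146 counts were tested with edgeR 4.0.16 under R 4.3.3 (quasi-likelihood F test, TMM scaling, filterByExpr), which kept 13129 genes. The standard error quoted for an edgeR fold change is its size divided by the square root of F. NCI-H1688 values were tested with limma 3.58.1 (empirical Bayes with an intensity trend) on log2(TPM + 1) for the 14741 genes with a mean of at least 1 TPM. Fold changes of that line are on the log2(TPM + 1) scale, which understates the change of low genes, and linear ratios are ratios of mean TPM. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called changed. Levels in NCI-H146 are CPM, the counts scaled by TMM totals. Means are given with the standard deviation (SD) over the 2 libraries of a group.

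There were 41 gene lists fixed before the data were examined. They were tested with camera (preset inter-gene correlation 0.01, at least 3 measured genes, adjusted over the lists of a line), which asks whether a list moves against the other genes. Camera with an estimated correlation and fry were run as alternatives. With an estimated correlation, camera uses the residual degrees of freedom of the fit, which are few with 4 libraries. Few lists could pass there whatever their shift, so a list that does not pass is not shown to be unchanged. The named genes follow a rule that was also fixed before the data were examined. For each line it takes KLF9, the 8 largest rises and 8 largest falls among called genes whose groups do not overlap and whose higher group averages at least 5 TPM or CPM (clone-style names and pseudogenes left out), and up to 3 called members of each list with the smallest adjusted p. Between lines it takes up to 10 genes called in the same direction and 6 called in opposite directions, ranked by the smaller of their 2 fold changes, under the same minimum level. Not every gene that these rules selected is reported here.

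Depth was 15406264 to 16109803 counts per library in NCI-H146. TPM keep no depth, but the spacing of low values gave the relative worth of 1 read in NCI-H1688, which lay between 0.927 and 1.035 of control replicate 1, so depth was similar in the 4 libraries. The reads of a gene in NCI-H1688 were estimated from this spacing and exon lengths of GENCODE 29. Counting intervals (95%, Poisson) on such estimates cover counting error only.

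The tests were tried on simulated data with 100 genes changed at each of 2 sizes. For NCI-H146, edgeR recovered 22% of genes changed by 1 on the log2 scale and 88% of those changed by 2, with 7 false calls among 13129 genes. DESeq2 1.42.0 recovered 32% and 86% with 20 false calls, and limma-voom 19% and 88% with 7. For NCI-H1688, limma recovered 79% and 98% with 13 false calls among 14741 genes. No list was called by camera when none was changed. Genes were simulated independently, so this does not test the preset correlation where genes of a list vary together. Estimated correlations in the data reached 0.9985, for the mitochondrially encoded list of NCI-H146.

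Libraries of a group did not hold identical values. The counts of the NCI-H146 pairs differed by more than sampling noise, with a chi-square of 31.9 per degree of freedom for the controls and 165 for the knockdowns. The labels call the libraries biological replicates and do not say whether they came from separate transductions, so p-values measure the spread between these libraries. The alternatives were other pseudocounts, filters, scalings, tests and thresholds, the replicate number as a block in NCI-H1688, and leaving out each library in turn, in which case the lone library of a group is assumed to vary like the pair of the other group. Leaving out the mitochondrially encoded genes in either line, and leaving out several gene lists in the comparison of the lines, were chosen after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for the rest. No column of the tables was left unused.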

Results

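KLF9, a Krüppel-like zinc-finger transcription factor, was targeted by shRNA in NCI-H1688 and NCI-H146 to ask how its depletion alters gene expression in small cell lung cancer cells. There were 8 libraries in 4 groups of 2, a control shRNA group and a KLF9 shRNA group in each line. The NCI-H146 libraries held 15406264 and 16109803 counts in the control group and 15601447 and 15413653 counts in the KLF9 shRNA group. The NCI-H1688 libraries were tabulated as TPM, with between 22866 and 23591 gene rows above 0 per library. Mitochondrially encoded genes took 14.3% to 17.7% of the TPM in NCI-H1688. In NCI-H146 they took 0.907% and 1.20% of the counts in the controls, 8.56% in KLF9 shRNA replicate 1 and 0.897% in replicate 2.

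The targeted gene was measured first. KLF9 lies on chromosome 9 at 70384597 to 70414624 (GRCh38, minus strand, protein coding). In NCI-H146 it fell from 64.4 ± 3.62 CPM in the control libraries to 28.6 ± 5.19 CPM in the knockdown libraries (SD, n = 2 each), a log2 fold change of -1.17 with a standard error of 0.283 and an edgeR adjusted p of 0.0131. The counts behind these levels were 994 and 1048 in the controls and 368 and 517 in the knockdowns. Without control replicate 2 or control replicate 3 the fold change was -1.08 or -1.23 and no longer passed (edgeR adjusted p = 0.255 and 0.101). In NCI-H1688 the direction went against the labels. KLF9 stood at 0.298 and 0.644 TPM in the control libraries and at 1.945 and 1.596 TPM in the libraries labelled KLF9 knockdown, and this difference did not pass the test (log2 fold change 0.92, standard error 0.279, limma adjusted p = 0.0951). All directions given for NCI-H1688 are therefore those of the libraries labelled KLF9 knockdown against the libraries labelled control.

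**Figure D1:**
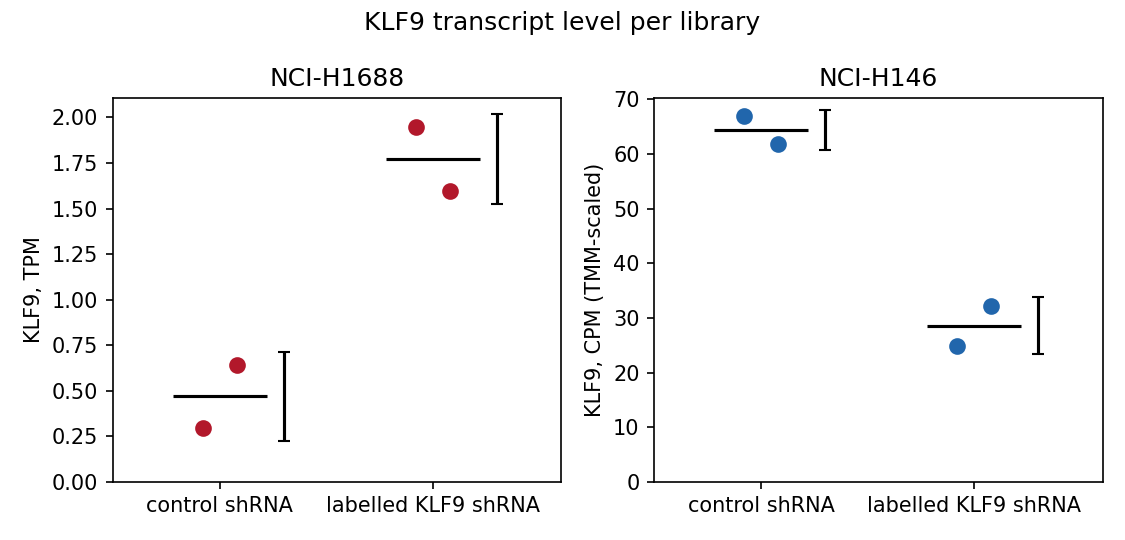
KLF9 level of each library (points) by group, in TPM for NCI-H1688 (left) and TMM-scaled CPM for NCI-H146 (right), with the group mean (horizontal line) and SD (bar beside it). The libraries labelled KLF9 knockdown lie above both controls in NCI-H1688 (1.945 and 1.596 against 0.298 and 0.644 TPM), where the test was not passed, and below both controls in NCI-H146 (24.9 and 32.2 against 66.9 and 61.8 CPM).

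In the NCI-H1688 libraries labelled KLF9 knockdown, the lists of interferon-stimulated, antigen presentation and hypoxia genes were called higher by camera with the preset correlation, and those of ribosome biogenesis and S phase genes lower. None of these calls held with an estimated correlation. S100A8 and S100A9, calcium-binding alarmins, showed the highest levels among the largest rises. S100A8 (chromosome 1, 153390032 to 153391188) went from 207 ± 21.7 to 2646 ± 76.7 TPM (SD, n = 2 each, 12.8-fold, limma adjusted p = 0.00116). S100A9 (chromosome 1, 153357854 to 153361027) went from 436 ± 24.5 to 3227 ± 99.8 TPM (7.40-fold, limma adjusted p = 0.00116). The neighbouring S100A7 rose 9.30-fold to 53.03 TPM. The glucose transporter gene SLC2A3 rose from 2.59 ± 0.360 to 41.9 ± 0.257 TPM and CA9, a carbonic anhydrase induced by hypoxia, from 2.71 ± 0.568 to 42.8 ± 0.829 TPM. Complement factor gene CFB rose 8.19-fold to 140.5 TPM and the serpin gene SERPINB4 8.09-fold to 47.3 TPM, with possible sharing of reads with its close paralog. MAGEA6, a cancer-testis antigen gene with near-identical paralogs, was listed at 0 in both controls and at 10.7 and 10.5 TPM in the libraries labelled KLF9 knockdown.

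Among the largest falls, the matrix glycoprotein gene THBS1 dropped from 291 ± 25.5 to 54.1 ± 0.0544 TPM and ESM1, an endothelial proteoglycan gene, from 13.5 ± 0.726 to 1.23 ± 0.150 TPM (limma adjusted p = 0.00155 and 0.00400). The AP-1 subunit gene FOSL1 fell from 70.3 ± 2.16 to 22.2 ± 0.671 TPM and the scaffold gene AKAP12 from 37.3 ± 2.13 to 11.5 ± 0.260 TPM. SEMA7A, a semaphorin gene, ended at 2.88 TPM, and IL1RL1, which encodes the interleukin-33 receptor, at 1.49 TPM. The small RNA genes BCYRN1 (219 ± 72.8 to 63.5 ± 1.97 TPM) and RNVU1-4 (9.05 and 26.5 TPM in the controls, listed at 0 in both libraries labelled KLF9 knockdown) also fell, with a wide spread between the controls.

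Of 39 measured interferon-stimulated genes, 25 rose and 0 fell in these libraries (28 rose when adjusted over the list alone), with a median log2 fold change of 0.75 (camera adjusted p = 1.088e-15). The list did not pass with an estimated correlation (adjusted p = 0.334). OASL rose from 18.6 ± 0.696 to 70.5 ± 1.55 TPM, IFIT3 from 17.2 ± 0.522 to 53.01 ± 0.0152 TPM and ISG15 from 132 ± 3.78 to 289 ± 12.5 TPM. In the antigen presentation list, 10 of 16 genes rose and 1 fell (the same numbers adjusted over the list alone, camera adjusted p = 1.204e-05, adjusted p = 0.367 with an estimated correlation). The class I gene HLA-B, whose reads can be shared with related genes, rose 2.93-fold. In the glycolysis and hypoxia list, 20 of 33 genes rose and 1 fell (23 and 2 adjusted over the list alone, camera adjusted p = 1.006e-10, adjusted p = 0.368 with an estimated correlation). NDRG1, a stress-induced member of this list, rose 4.54-fold to 201 TPM.

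Other lists called higher by camera in these libraries likewise did not pass with an estimated correlation. The glucocorticoid-induced list had 10 rises and 1 fall among 16 genes (11 and 2 adjusted over the list alone, camera adjusted p = 5.005e-05, adjusted p = 0.368 with an estimated correlation). DDIT4, an inhibitor of mTOR signalling, rose from 242 ± 15.7 to 542 ± 3.73 TPM. The circadian clock list had 9 rises and 0 falls among 15 genes (9 and 1 adjusted over the list alone, camera adjusted p = 0.000947, adjusted p = 0.334 with an estimated correlation). The clock output factor gene DBP rose 3.95-fold and the period gene PER2 2.20-fold. The NF-kB list had 10 rises and 3 falls among 24 genes (12 and 4 adjusted over the list alone, camera adjusted p = 0.00219, adjusted p = 0.334 with an estimated correlation). The superoxide dismutase gene SOD2 rose from 127 ± 2.33 to 466 ± 3.62 TPM. The inhibitor gene NFKBIA rose 2.23-fold and the chemokine gene CCL5 5.79-fold. Among 27 immediate early genes, 12 rose and 4 fell (14 and 6 adjusted over the list alone, camera adjusted p = 0.000635, adjusted p = 0.334 with an estimated correlation). EGR1 and ZFP36 rose 1.83-fold and 2.05-fold in that list while FOSL1 fell. The epithelial adhesion list rose by camera (11 rises and 3 falls among 31 genes, 12 and 3 adjusted over the list alone, adjusted p = 0.00218), and did not pass with an estimated correlation (adjusted p = 0.489). Its members moved apart, since the epithelial factor gene ELF3 rose 4.42-fold while the simple-epithelium keratin genes KRT8 (1215 ± 17.8 to 643 ± 19.3 TPM) and KRT18 (1072 ± 28.99 to 614 ± 4.04 TPM) fell.

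The MYC target and ribosome biogenesis list fell in these libraries, with 27 falls and 0 rises among 36 genes (30 falls and 1 rise adjusted over the list alone) and a median log2 fold change of -0.56 (camera adjusted p = 2.007e-12, adjusted p = 0.334 with an estimated correlation). ODC1, the rate-limiting enzyme of polyamine synthesis, fell from 90.4 ± 3.88 to 45.0 ± 3.40 TPM and MRTO4 from 27.3 ± 0.394 to 13.1 ± 0.832 TPM, while NOLC1 ended at 0.681 of its control mean. Of 42 S phase genes 14 fell and 0 rose (27 falls adjusted over the list alone, camera adjusted p = 1.82e-10, adjusted p = 0.334 with an estimated correlation). Among them were the ribonucleotide reductase gene RRM2 (152 ± 3.92 to 87.9 ± 0.425 TPM) and UHRF1 (45.7 ± 0.200 to 27.4 ± 0.0104 TPM). Of 52 G2 and M phase genes 17 fell and 0 rose (22 falls adjusted over the list alone, camera adjusted p = 1.811e-07, adjusted p = 0.334 with an estimated correlation). The mitotic genes CDC20 and TUBB4B were at 0.680 and 0.632 of their control means. In the nuclear-encoded respiratory chain list 12 of 74 genes fell and 0 rose (12 adjusted over the list alone, camera adjusted p = 1.204e-05, adjusted p = 0.622 with an estimated correlation). SDHA and UQCR10 were at 0.531 and 0.575 of their control means. The list was not called after quantile normalization. The DNA repair list had 6 falls and 1 rise among 34 genes (11 and 3 adjusted over the list alone, camera adjusted p = 0.00380, adjusted p = 0.334 with an estimated correlation). In it, the helicase gene ERCC2 fell and the methyltransferase gene MGMT rose.

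Smaller list changes in the same libraries depended on the setting. Heat shock genes had 8 falls and 3 rises among 16 (10 and 3 adjusted over the list alone, camera adjusted p = 0.0180, adjusted p = 0.552 with an estimated correlation). The chaperone gene HSP90AA1 fell from 904 ± 39.9 to 393 ± 8.27 TPM, whereas HSPB1 and HSPA1B rose 1.56-fold and 1.46-fold. This call was lost without KLF9 shRNA replicate 2, at a mean of at least 5 TPM and after quantile normalization. Fatty acid synthesis genes had 3 rises and 0 falls among 18 (the same adjusted over the list alone, camera adjusted p = 0.0135, adjusted p = 0.531 with an estimated correlation). The desaturase gene SCD and its regulator SREBF1 rose. Among the settings tried for the gene-level fit, this call was lost only without KLF9 shRNA replicate 2. The mitochondrially encoded list had 1 rise among 13 genes, MT-CO1 (4 rises adjusted over the list alone, camera adjusted p = 0.0204, adjusted p = 0.531 with an estimated correlation). It was not called without KLF9 shRNA replicate 1, and in 4 of 8 other settings (TMM scaling, limma without a trend, no filter on low values and quantile normalization). The cytosolic ribosomal protein list, with 3 falls among 71 genes including RPL6 (0 adjusted over the list alone, camera adjusted p = 0.0432, adjusted p = 0.794 with an estimated correlation), had a median of -0.060. The median of the cytosolic ribosomal proteins became 0.0089 with the mitochondrially encoded genes left out and 0.0052 without control replicate 2, and the list was called in neither case. It kept its call in 3 of 9 settings with all libraries and in 1 of the 4 fits with a library left out (without control replicate 1). Of 18 leukocyte markers only 3 were measured, of which CD14 (0.632 ± 0.0447 to 6.78 ± 0.437 TPM) and LAPTM5 (8.52 ± 0.160 to 14.9 ± 0.490 TPM) rose (the same 2 adjusted over the list alone, camera adjusted p = 0.0135, adjusted p = 0.368 with an estimated correlation). The leukocyte list was not called with no filter on low values.

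In total 2364 of 14741 genes were called in NCI-H1688, 939 higher and 1425 lower in the libraries labelled KLF9 knockdown (limma). Of these, 265 rose and 94 fell by at least 1 on the log2 scale. All 2364 had groups that did not overlap, as did 62.7% of all tested genes, against 33.3% expected by chance for 2 against 2. The camera test called 18 of 39 lists, 11 up and 7 down, and 0 with an estimated correlation, where 1 list had an unadjusted p under 0.05. With 3 libraries the count of called genes was 0 without KLF9 shRNA replicate 1 or replicate 2 (limma, 3327 and 3298 genes at an unadjusted p under 0.05), 24 without control replicate 1 and 17 without control replicate 2. The split between higher and lower genes moved to 1133 and 1108 with the mitochondrially encoded genes left out, and to 487 and 345 in limma without a trend.

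In NCI-H146 knockdown libraries, the lists of immediate early genes, other Krüppel-like factors, clock genes and heat shock genes were called lower by camera with the preset correlation, and those of neuroendocrine and respiratory chain genes higher. None of these calls held with an estimated correlation. KLF5 (chromosome 13, 73054976 to 73077542), a Krüppel-like factor of proliferating epithelium, fell from 154 ± 46.7 to 11.5 ± 3.88 CPM (SD, n = 2 each, log2 fold change -3.75, standard error 0.349, edgeR adjusted p = 6.93e-05). KLF10, induced by TGF-beta, fell from 204 ± 11.1 to 29.2 ± 5.27 CPM (log2 fold change -2.81, edgeR adjusted p = 0.000135). KLF4 fell from 12.2 and 4.13 CPM in the controls to 0 and 0.811 CPM. MXD1, a MYC antagonist, dropped from 67.2 ± 18.5 to 7.30 ± 0.00904 CPM and the splicing regulator RBM47 from 5.33 ± 1.61 to 0.286 ± 0.213 CPM. RGS2, a regulator of G protein signalling, went from 54.4 and 23.3 CPM in the controls to 2.23 and 3.99 CPM. The falls of the chaperone gene CRYAB (99.0 and 33.4 CPM to 0 and 6.17), the globin gene HBA2 (84.2 and 28.7 CPM to 3.25 and 7.48), whose reads can be shared with its copy, and the stress gene ZFAND2A (85.6 and 32.1 CPM to 6.29 and 6.61) came with controls that differed widely from each other.

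The largest rises in this line were mostly of genes at low levels. The NADPH oxidase subunit gene CYBA rose from 0.501 ± 0.0421 to 6.46 ± 3.39 CPM and the synaptic gene CPLX3 from 1.07 ± 0.1004 to 11.2 ± 2.85 CPM (edgeR adjusted p = 0.00110 and 0.000444). MAPK8IP2, a neuronal kinase scaffold gene, rose 9.76-fold to 12.3 CPM and the neuropeptide precursor gene VGF from 2.73 ± 0.611 to 18.1 ± 4.37 CPM. The chemokine receptor gene ACKR3 reached 18.8 ± 10.5 CPM and the matrix gene FBLN2 6.85 ± 2.04 CPM. MT-CO1 and MT-ND6, encoded by mitochondrial DNA, were also among the 8 largest rises. MT-CO1 stood at 2090 and 2778 CPM in the controls, 30937 CPM in knockdown replicate 1 and 3104 CPM in replicate 2. The mitochondrially encoded list had 10 rises and 0 falls among 13 genes (12 rises adjusted over the list alone, camera adjusted p = 9.994e-05, adjusted p = 0.8165 with an estimated correlation). This rested on 1 library, since without knockdown replicate 1 the list median changed from 2.10 to -0.12 and the list was not called.

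Among 28 immediate early genes 14 fell and 0 rose in NCI-H146 (17 falls adjusted over the list alone), with a median log2 fold change of -1.06 (camera adjusted p = 2.022e-09, adjusted p = 0.8165 with an estimated correlation). EGR1 fell from 28.96 ± 12.3 to 4.52 ± 1.27 CPM. The orphan nuclear receptor genes NR4A2 and NR4A3 fell from 10.97 ± 2.58 to 1.38 ± 0.447 CPM and from 7.001 ± 1.81 to 0.967 ± 0.219 CPM. Of 19 Krüppel-like and SP factors other than KLF9, 9 fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 4.41e-06, adjusted p = 0.8165 with an estimated correlation). Of 17 circadian clock genes 8 fell and 0 rose (9 falls adjusted over the list alone, camera adjusted p = 3.895e-05, adjusted p = 0.8165 with an estimated correlation). Those that fell included the clock repressor genes NR1D1 (82.2 ± 35.9 to 15.6 ± 0.350 CPM) and NR1D2 (148 ± 20.4 to 47.2 ± 4.38 CPM) and the activator gene BMAL1 (12.4 ± 3.83 to 2.68 ± 0.534 CPM). The NF-kB list had 5 falls and 0 rises among 12 genes (9 falls adjusted over the list alone, camera adjusted p = 0.000987, adjusted p = 0.8165 with an estimated correlation). The feedback inhibitor gene TNFAIP3 fell from 10.9 ± 0.349 to 2.39 ± 0.505 CPM. Glucocorticoid-induced genes had 7 falls and 0 rises among 17 (8 falls adjusted over the list alone, camera adjusted p = 0.0201, adjusted p = 0.8165 with an estimated correlation). TSC22D3 and SGK1 were among those that fell. This call was lost without control replicate 2 or knockdown replicate 1.

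Lists of stress response genes were also called lower by camera in this line, with the preset correlation only. The heat shock list had 6 falls and 0 rises among 16 genes (6 adjusted over the list alone, camera adjusted p = 0.00194, adjusted p = 0.8165 with an estimated correlation). DNAJB1 stood at 1038 and 370 CPM in the controls and at 120 and 184 CPM in the knockdowns, and the co-chaperone genes HSPH1 and BAG3 fell from 2669 ± 1315 to 678 ± 59.5 CPM and from 413 ± 227 to 86.8 ± 17.6 CPM. The endoplasmic reticulum stress list had 6 falls and 0 rises among 20 genes (6 adjusted over the list alone, camera adjusted p = 0.00722, adjusted p = 0.8165 with an estimated correlation). HERPUD1 fell from 596 ± 339 to 139 ± 24.7 CPM and DNAJB9 from 65.2 ± 29.9 to 15.5 ± 3.14 CPM. The controls themselves differed by a median log2 ratio of 0.857 in the heat shock list and 0.703 in the endoplasmic reticulum stress list (replicate 2 over replicate 3), more than the median fold changes of -0.533 and -0.339. Neither list was called without control replicate 2. The ATF4 list had 5 falls, DDIT3 among them, and 0 rises in 24 genes (6 falls adjusted over the list alone, camera adjusted p = 0.0120, adjusted p = 0.8165 with an estimated correlation). The cholesterol synthesis list had 10 falls, INSIG1 and HMGCS1 among them, and 2 rises in 23 genes (10 and 4 adjusted over the list alone, camera adjusted p = 0.0236, adjusted p = 0.8165 with an estimated correlation). Neither the ATF4 nor the cholesterol synthesis list was called without control replicate 2 or knockdown replicate 1, and the cholesterol synthesis list was not called in limma-voom.

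The neuroendocrine and neuronal list had 10 rises and 1 fall among 26 measured genes in NCI-H146 (11 and 1 adjusted over the list alone, median log2 fold change 0.70, camera adjusted p = 0.000987, adjusted p = 0.8165 with an estimated correlation). The 3 called members with the smallest adjusted p stayed at low levels in controls and knockdowns. The granule protein gene CHGA was at 0.366 ± 0.232 and 2.78 ± 0.482 CPM, the prohormone convertase gene PCSK2 at 0.960 ± 0.310 and 5.22 ± 0.852 CPM and RUNDC3A at 0.509 ± 0.137 and 3.15 ± 0.0444 CPM. Some other members were not low, such as UCHL1 at 678 ± 41.7 CPM and ENO2 at 127 ± 7.78 CPM in the controls. The list was not called when genes needed at least 50 counts per group. In the list of non-neuroendocrine markers 5 of 24 genes fell and 0 rose (5 adjusted over the list alone, camera adjusted p = 0.0123, adjusted p = 0.8165 with an estimated correlation). REST, a repressor of neuronal genes, fell from 56.6 ± 6.49 to 24.3 ± 5.39 CPM, and ANXA1 also fell. That call was lost without control replicate 2. The nuclear-encoded respiratory chain list had 12 rises and 0 falls among 74 genes (19 rises adjusted over the list alone, median 0.59, camera adjusted p = 7.745e-07, adjusted p = 0.8165 with an estimated correlation). ATP5MC1 and NDUFA8 rose 2.63-fold and 2.62-fold and were higher in knockdown replicate 2 than in replicate 1. The MYC target and ribosome biogenesis list had 6 rises and 0 falls among 37 genes (6 adjusted over the list alone, camera adjusted p = 0.01002, adjusted p = 0.8165 with an estimated correlation). It included the pyrimidine synthesis gene CAD and RRP9, and was not called without knockdown replicate 1 or control replicate 3.

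The cell cycle lists moved apart in NCI-H146. The S phase list had 5 rises and 1 fall among 42 genes (the same adjusted over the list alone, camera adjusted p = 0.0460, adjusted p = 0.851 with an estimated correlation). UHRF1 and the helicase gene MCM5 rose 2.64-fold and 2.17-fold. The G2 and M phase list had 5 falls and 2 rises among 52 genes (the same adjusted over the list alone, camera adjusted p = 0.0236, adjusted p = 0.8165 with an estimated correlation). GAS2L3 fell from 91.1 ± 9.88 to 16.07 ± 2.63 CPM, and the spindle checkpoint kinase gene TTK also fell. The histone list had 2 falls among 9 genes (5 falls and 1 rise adjusted over the list alone, camera adjusted p = 0.0102, adjusted p = 0.8165 with an estimated correlation), including H2BC21. The p53 target list had 7 falls and 0 rises among 22 genes (9 and 3 adjusted over the list alone, camera adjusted p = 0.0236, adjusted p = 0.8165 with an estimated correlation), including CCNG1. The TGF-beta and BMP list had 7 falls, ID2 among them, and 2 rises, BMP7 among them, in 28 genes (the same adjusted over the list alone, camera adjusted p = 0.0236, adjusted p = 0.8165 with an estimated correlation). The matrix and mesenchymal list had 5 falls, including THBS1 and the transcription factor genes SNAI1 and ZEB1, and 2 rises in 25 genes (7 and 2 adjusted over the list alone, camera adjusted p = 0.0395, adjusted p = 0.8165 with an estimated correlation). None of these 6 lists was called without control replicate 2, and of them only the G2 and M phase list was called without knockdown replicate 1. That list was not called without knockdown replicate 2, nor the matrix list without control replicate 3. With all libraries, the p53 target list was not called when genes needed at least 50 counts per group or with no filter on low counts, nor the matrix list in limma-voom or with no filter. The controls differed by a median log2 ratio of 0.874 in the histone list, whose median fold change was -1.02.

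In total 2250 of 13129 genes were called in NCI-H146, 1052 higher and 1198 lower in the knockdown libraries (edgeR). Of these, 858 rose and 974 fell by at least 1 on the log2 scale, and 2233 had groups that did not overlap, as did 62.5% of all tested genes. The camera test called 20 of 39 lists, 5 up and 15 down, and 0 with an estimated correlation, where 1 list had an unadjusted p under 0.05. The number of called genes was 51 without control replicate 2, 537 without control replicate 3, 5026 without knockdown replicate 1 and 2663 without knockdown replicate 2, and 6 of the 20 lists were called in all 4 of these fits.

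Most genes called in both lines went in opposite directions. Of 11110 genes tested in both, 75 were called in the same direction and 333 (81.6%) in opposite directions, taking the NCI-H1688 libraries as labelled. There were 128 genes higher in NCI-H1688 and lower in NCI-H146, where independent lists would share 62.1, and 205 genes lower in NCI-H1688 and higher in NCI-H146, where independent lists would share 99.3 (two-sided Fisher's exact test, p = 4.237e-16 and 3.603e-26). Genes higher in both numbered 38 against 53.8 for independent lists, and genes lower in both 37 against 115 (two-sided Fisher's exact test, p = 0.0188 and 1.069e-19). The Fisher tests count genes as independent, which they are not, so their p-values do not measure the spread between libraries. Across these genes, which are not independent replicates, the log2 fold changes of the lines correlated with Pearson r = -0.167 and Spearman rho = -0.189. If the NCI-H1688 labels were exchanged, the 333 genes would go in the same direction and the 75 in opposite directions. Both correlations would then be positive.

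Among the genes called in opposite directions were ARRDC3, an arrestin-domain gene, at 4.88-fold in NCI-H1688 and 0.268 of the control mean in NCI-H146, and the transcriptional repressor gene BCL6, at 3.85-fold and 0.254. NDRG1 was at 4.54-fold and 0.299, and the chemokine gene CXCL11 at 4.39-fold and 0.310. NR4A2 was at 3.19-fold and 0.125, and CCNG2, a cyclin linked to cell cycle arrest, at 2.57-fold and 0.246. Among the genes that fell in both lines were THBS1 (0.186 of the control mean in NCI-H1688 and 0.127 in NCI-H146), HSP90AA1 (0.435 and 0.362), the matricellular gene CCN1 (0.486 and 0.457) and PMEPA1, a regulator of TGF-beta signalling (0.551 and 0.315). Genes higher in both lines included the class I gene HLA-F (2.94-fold and 2.31-fold), TCIM (5.23-fold and 2.06-fold), SEZ6L2 (2.11-fold and 2.17-fold), FRMD8 (2.02-fold and 2.22-fold), RAPGEFL1 (2.10-fold and 2.13-fold) and NUDT18 (2.27-fold and 5.84-fold). The difference between the lines was not tested, since their tables had been normalized separately. With 1 library left out, the number of genes called in the same direction was 0 without either NCI-H1688 KLF9 shRNA library, 1 without either NCI-H1688 control, 270 and 83 without NCI-H146 knockdown replicate 1 and 2, and 3 and 22 without NCI-H146 control replicate 2 and 3. The number called in opposite directions was 0 without either NCI-H1688 KLF9 shRNA library, 2 and 1 without NCI-H1688 control replicate 1 and 2 (66.7% and 50% of the shared calls), 575 and 414 without NCI-H146 knockdown replicate 1 and 2 (68.0% and 83.3%), and 8 and 80 without NCI-H146 control replicate 2 and 3 (72.7% and 78.4%).

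**Figure D2:**
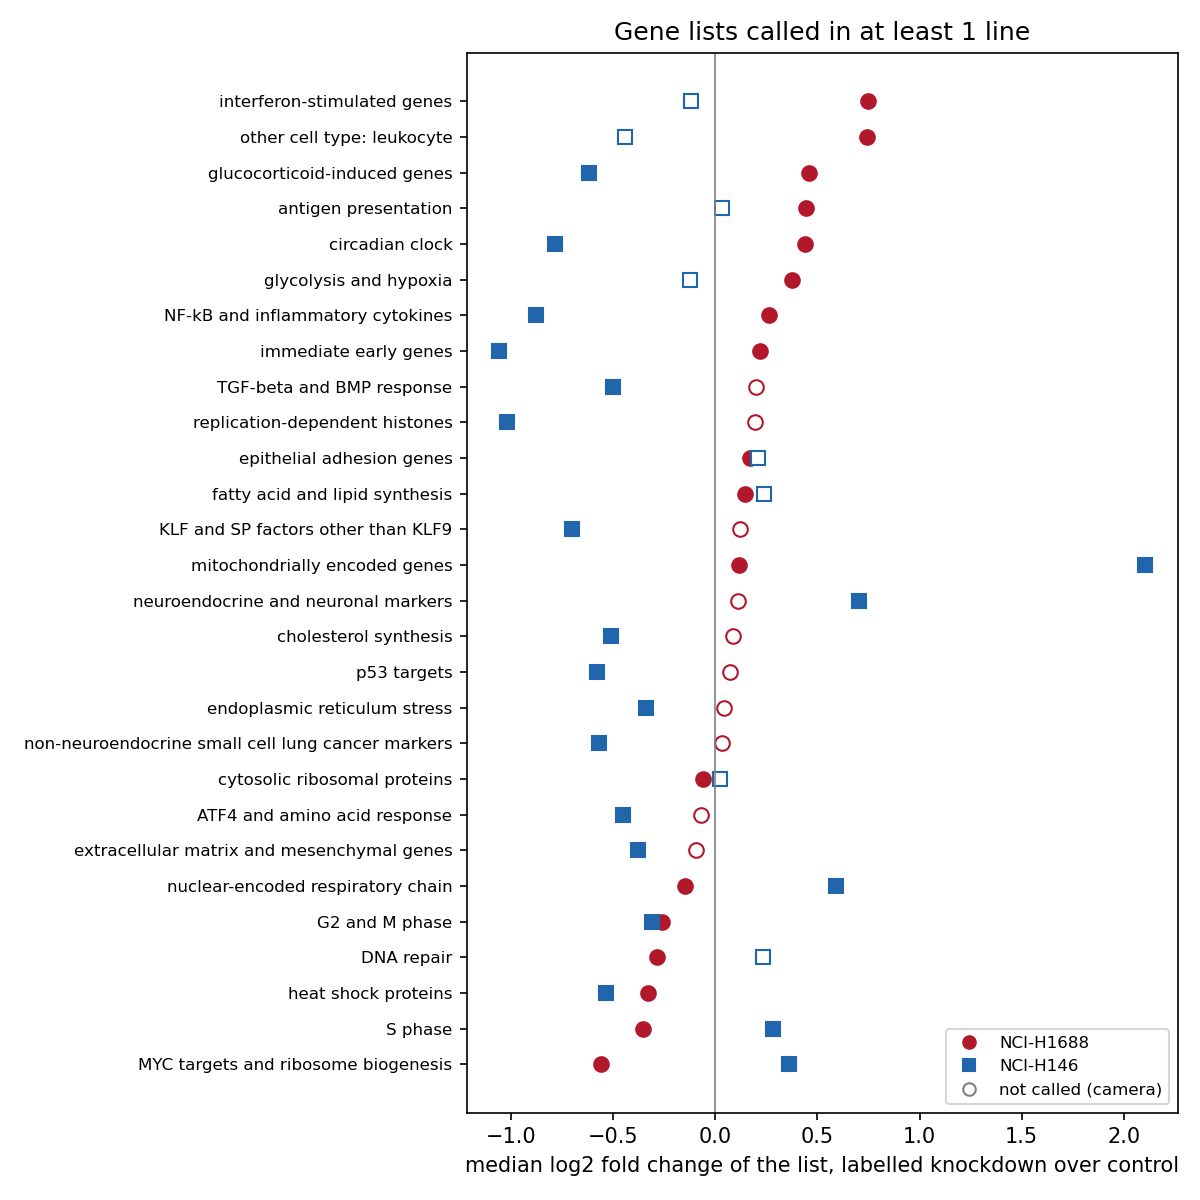
Median log2 fold change of each gene list called in at least 1 line (horizontal axis, log2 units, labelled knockdown over control), for NCI-H1688 (circles) and NCI-H146 (squares), filled where camera with the preset correlation called the list and open where it did not. The immediate early, circadian clock, NF-kB and glucocorticoid-induced lists lie above 0 in NCI-H1688 and below 0 in NCI-H146, and the MYC and S phase lists the other way round; no list was called with an estimated correlation, and the square of the mitochondrially encoded list (2.10) rests on 1 library.

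**Figure D3:**
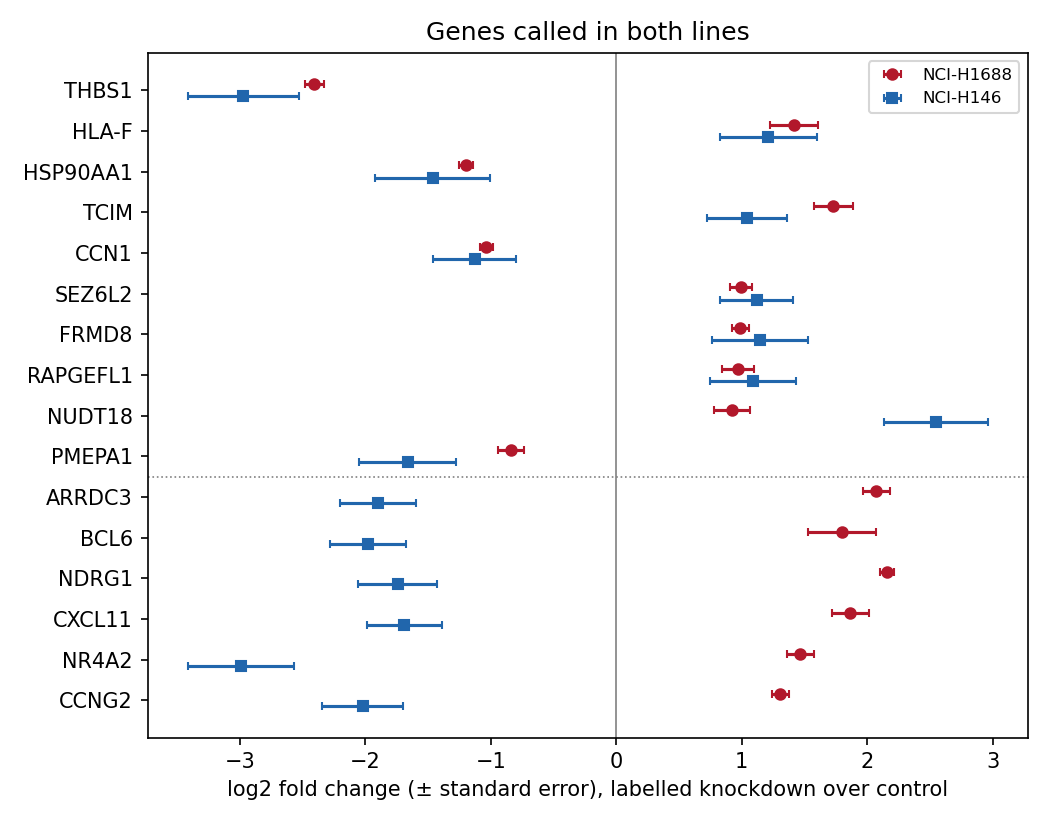
Log2 fold change with its standard error (horizontal axis, labelled knockdown over control) of the 10 genes called in the same direction (above the dotted line) and the 6 genes called in opposite directions (below it), for NCI-H1688 (circles) and NCI-H146 (squares). Each of the 6 lower genes has its circle above 0 and its square below 0, as ARRDC3 at 2.07 and -1.90.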

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

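The gene and list tests in this part were planned, and the tests of counting error and of exchanged labels were chosen after the values they bear on were seen. What drew attention here is that every library of 1 line moved one way and every library of the other line the opposite way, and none of these differences between the lines was tested.

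KLF9 had a log2 fold change of 0.92 in NCI-H1688 (not past the threshold), in the libraries labelled KLF9 knockdown against the controls, and of -1.17 in NCI-H146. The sizes are not comparable, since the NCI-H1688 value is on the log2(TPM + 1) scale, which understates low genes. The ratios of group means were 3.76 in NCI-H1688 and 0.444 in NCI-H146. Counting error at the low KLF9 level is argued against, because the lowest counting bound of the libraries labelled KLF9 knockdown, 101 estimated reads, lay above the highest bound of the controls, 67.1 reads. Control and knockdown labels exchanged in NCI-H1688 is a candidate explanation, with 81.6% of the shared calls in opposite directions as labelled. After an exchange that 81.6% would go in the same direction. That share is part of what raised this explanation. An exchange cannot be told apart from a difference between the lines, since each line has 1 set of labels and its own table. Knockdown that failed or was lost in NCI-H1688 would not by itself raise KLF9 above the controls or set the shared calls in opposite directions. Such knockdown stays open only together with another difference between the groups, which was not tested. No biological explanation was tested.

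Other genes showed the same opposition. NDRG1 had log2 fold changes of 2.16 in NCI-H1688 and -1.74 in NCI-H146. ARRDC3 had 2.07 and -1.90, and BCL6 had 1.80 and -1.98. CXCL11 had 1.87 and -1.69, and CCNG2 had 1.31 and -2.02. NR4A2 had 1.47 and -2.99, and EGR1 had 0.87 and -2.68. UHRF1 went the other way, with -0.72 and 1.40.

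Several lists called in both lines by camera with a preset correlation also had medians of opposite sign in every library labelled knockdown. None of these lists passed camera with an estimated correlation in either line (smallest adjusted p = 0.334 in NCI-H1688 and 0.8165 in NCI-H146). That test rests on few residual degrees of freedom, so it decides little. The circadian clock list did not pass although its estimated correlation in NCI-H1688, -0.045, lay below the preset 0.01. The glucocorticoid-induced list had a median log2 fold change of 0.46 in NCI-H1688 and -0.62 in NCI-H146, and the circadian clock list 0.44 and -0.79. The NF-kB list had medians of 0.26 and -0.88, and the immediate early list 0.22 and -1.06. The S phase list had medians of -0.36 and 0.28, and the MYC target and ribosome biogenesis list -0.56 and 0.36. The nuclear-encoded respiratory chain list had -0.15 and 0.59. In NCI-H146 the S phase median was 0.46 in knockdown replicate 1 and 0.093 in replicate 2, each against the control mean. The controls differed by a median log2 ratio of -0.227 in that list (replicate 2 over replicate 3). The NCI-H146 calls of the S phase, MYC target and glucocorticoid-induced lists were lost without some single libraries.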

How the results depend on the processing

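In NCI-H1688, 2364 genes were called, and the number was 832 in limma without a trend, 947 with no filter on low values, 359 with a fold change of at least 1 on the log2 scale and 285 at an adjusted p under 0.01. The last 2 are stricter thresholds, and the causes of the first 2 were not tested. Leaving out 1 library gave 0 to 24 called genes. With the replicate number as a block (replicate block) 1219 genes were called, and the numbers share nothing else, with a correlation of -0.0049 between same-numbered deviations. No paired analysis was run in NCI-H146, whose groups share only 1 number. KLF9 stayed higher and not called in NCI-H1688 in every fit that kept it; it was filtered out at a mean of 5 TPM and without either KLF9 shRNA library.

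In NCI-H146, 2250 genes were called, and the number was 1320 with library totals only (the cause was not tested), 494 at an adjusted p under 0.01 and 51 to 5026 with 1 library left out. Without mitochondrially encoded genes, an alternative chosen after seeing the data, it was 2195. KLF9 kept its call under every scaling, filter and test, and with 1 library left out its log2 fold change ranged from -1.37 to -0.98, losing the call without either control. Of the named called genes, 61 of 72 in NCI-H1688 and 65 of 74 in NCI-H146 kept their call under all settings other than leaving out a library, and 0 and 17 under every such omission; no named gene reversed.

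The 18 lists called in NCI-H1688 became 0 with an estimated correlation, 21 in the directional fry test (14 of the 18 among them) and 34 in the mixed fry test. The 20 in NCI-H146 became 0 with an estimated correlation, 0 in the directional fry test (6 lists at an unadjusted p under 0.05), 19 in the mixed fry test and 8 to 21 with 1 library left out. The count of 0 with an estimated correlation decides little, since that test rests on few residual degrees of freedom. Medians that reversed with 1 library left out were those of the cytosolic ribosomal protein list in NCI-H1688 (-0.13 to 0.0052) and the mitochondrially encoded list in NCI-H146 (-0.12 to 2.965). Of the lists, 12 in NCI-H1688 and 5 in NCI-H146 kept their call in every gene-level setting.

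Between lines, the 75 genes called in the same direction became 34 with limma on log2 values in both lines and 0 to 270 with 1 library left out, and r stayed negative throughout, at -0.20 to -0.11 with 1 library left out.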

Other observations

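The gene and list tests in this part were planned, and the test of transcript length was written before its result was seen. The tests of depth, of cells other than the named lines, of KLF9 knockdown as the cause of the mitochondrially encoded counts, and of the effect of those counts on the number of called genes were chosen after the result was seen. Further lists described pathways that did not pass as a whole. In the NCI-H1688 libraries labelled KLF9 knockdown, 3 of 16 Notch pathway genes rose and 0 fell (3 adjusted over the list alone, camera adjusted p = 0.0598). The receptor gene NOTCH3 rose from 11.3 ± 1.05 to 36.3 ± 0.993 TPM (SD, n = 2 each) and the feedback gene NRARP rose 2.09-fold. In the WNT list 3 of 20 genes fell and 0 rose (5 falls adjusted over the list alone, camera adjusted p = 0.0899), namely the antagonist gene DKK1 (150.2 ± 6.31 to 64.9 ± 2.64 TPM) and the ligand genes WNT7A and WNT7B. The NRF2 and redox list had 6 rises and 4 falls among 27 genes (6 and 8 adjusted over the list alone, camera adjusted p = 0.937), with the aldo-keto reductase genes AKR1C2 and AKR1C3, which have near-identical relatives, at 4.56-fold and 2.79-fold.

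In NCI-H146, 3 of 18 epithelial adhesion genes rose and 0 fell in the knockdown libraries (3 adjusted over the list alone, camera adjusted p = 0.338). These were the E-cadherin gene CDH1 (0.649 ± 0.251 to 2.55 ± 0.606 CPM), OVOL2 and SPINT2, while the E-cadherin repressor genes SNAI1 and ZEB1 fell. The WNT list had 3 rises and 4 falls among 25 genes (4 and 5 adjusted over the list alone, camera adjusted p = 0.568), with rises of the target gene APCDD1 (278 ± 60.0 to 765 ± 196 CPM) and the ligand gene WNT5B.

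Many neuroendocrine markers stood at low levels in both lines. In the NCI-H1688 controls 37 of the 47 listed markers averaged under 1 TPM, and in the NCI-H146 controls 16 of the 34 analysed markers averaged under 1 CPM, with NEUROD1 at 0.627 CPM, and SYP averaged 1.48 CPM. Other markers of the list were not low, since 5 averaged at least 5 TPM in NCI-H1688 and 10 at least 5 CPM in NCI-H146. UCHL1 averaged 678 ± 41.7 CPM and ENO2 127 ± 7.78 CPM in the NCI-H146 controls. The count of genes averaging 5 or more, at least 10350 in each line, cannot test whether depth was too low to measure the markers. TPM and CPM are shares of a total, so that count depends little on depth. The NCI-H146 libraries held 15406264 to 16109803 counts. In NCI-H1688 control replicate 1, KLF9 at 0.298 TPM had an estimated 24 reads. Low depth was not tested further and stays open. Basal and intestinal markers were picked after their levels were seen, and 5 basal markers in NCI-H1688 and 1 intestinal marker in NCI-H146 (CDX2) lay above the 95th percentile of listed genes. In the NCI-H1688 controls KRT17 averaged 2500 ± 120 TPM, KRT5 555 ± 19.3 TPM and S100A2 3374 ± 216 TPM, and in the NCI-H146 controls CDX2 averaged 3341 ± 397 CPM. Cells other than the named lines are a candidate explanation that cannot be told apart from lines that express these genes, since no genotype or reference profile of the lines was used here, and no biological explanation was tested.

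Mitochondrially encoded genes took 8.56% of the counts in NCI-H146 knockdown replicate 1. KLF9 knockdown as the cause is argued against by knockdown replicate 2, at 0.897%, below both controls (0.907% and 1.20%). Transcript length bias in that library is argued against too. Across 12442 genes the log2 ratio of knockdown replicate 1 to replicate 2 had a Spearman rho of 0.059 with exon length, whereas the pair of controls had a rho of -0.357. The controls enter every fold change of this line, and the effect of their difference on the calls was not tested. The mitochondrially encoded counts did not set the number of called genes, which was 2195 without them and 2250 with them. Differences in RNA handling or in the state of that culture stay open. The list of nuclear-retained and RNA quality transcripts, with 1 rise and 1 fall among 14 genes (camera adjusted p = 0.4997), had a median log2 ratio of -0.522 for knockdown replicate 1 over replicate 2 and of 0.280 between the controls. Other lists differed as much between the knockdown replicates, such as the ATF4 list at -0.624, so this value decides nothing.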
